A study of Nematostella vectensis with 66 samples.

How the data were processed

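Whole-animal RNA of adult Nematostella vectensis was sequenced in 66 libraries. Per the labels, 200 laboratory-reared animals were moved to the field in 10 pens at a salinity matched to the site. By the stated protocol, 4 animals of each hour became individual libraries (letters A to D) and 6 were pooled by 2 (letters E to G). The labels of ZT4 depart from this, since its library D is labelled as a pool. The label was followed, and whether it is right was not settled. Per the labels' protocols, RNA was extracted from preserved whole animals and libraries were prepared after a protocol of Meyer and colleagues. The labels do not say from which pen each animal came, so the pen and the hour may be confounded. The replicates are separate animals or separate pools of animals, per the labels.

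The values are whole-number counts per gene model, as deposited in one table of 24265 gene models and 66 libraries. Per the labels, the genome was that of Putnam and colleagues, and Bowtie2 was the aligner per the submitters' processing notes, with no version given. The counting tool, the annotation version and the treatment of duplicate reads were not given in the sources used here. A reference table of another assembly (jaNemVect1.1) was searched for the gene model identifiers, and 0 matched. Gene names, and the 28 gene lists fixed before the data were examined, were therefore not used here, and no test of a gene list was run. Reads shared between closely related gene models could have been split or dropped in counting, so values of members of gene families are uncertain. Whether molecular identifiers were used was not given in the sources used here, so counts may include amplification, and the printed errors are spreads between libraries.

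Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust estimation and TMM normalisation factors. Genes were kept with edgeR's filter by expression (minimum count 10, hour as group), which left 10916 gene models holding 97.2% of all counts. The adjusted p is that of Benjamini and Hochberg, with a threshold of 0.05. The time effect was a test on 9 degrees of freedom over the 10 hours with sample type as covariate and all 66 libraries, leaving 55 residual degrees of freedom. The contrast of ZT12 with ZT3, the 9 steps between consecutive hours and the difference of pools from individuals came from the same fit. Each step was adjusted over genes on its own. Trends came from a fit with linear and quadratic terms in ZT hour. It took libraries as replicates and had no term for shifts shared by the libraries of an hour. The interaction of hour and sample type had its own fit. CPM values were computed with TMM factors, and log2 CPM with a prior count of 2. The measures of spread were edgeR's common dispersion in individual and pooled libraries fitted apart, and residual variances of log2 CPM around the hour mean. The latter were compared by permuting sample type within the hour 10000 times, or 1000 times under other settings.

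The leading axis of variation was the first singular vector of log2 CPM residuals after removing hour and sample type, and each library's score is its projection on that axis. Residuals were not scaled per gene, so genes with a large residual SD weigh most in the axis. A score is a sum over genes in log2 CPM units and has no absolute zero. K-means profiles used 4 centres, a fixed seed and hourly fitted values standardised per gene.

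Genes named in the text followed a rule set before the data were examined. With no names at hand it allowed at most 2 identifiers that rose and 2 that fell for each comparison. These were the smallest p for the time effect, the steepest slope for the linear trend, the largest coefficient for the quadratic term and the largest residual SD between individuals. All designs and most other settings were also set before the data were examined. These other settings were DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, DESeq2's size factors, no filter on low counts, the replicate letter as a block, no covariate, no ZT4, and each library left out in turn. Chosen after the data were seen were fits without 4 libraries that shared a block of genes, with the axis score as covariate, with counts thinned to at most 424453 per library (the second lowest total, so that ZT4 individual C kept its 251647), and with each library left out in the fits of a single sample type. A further setting, without libraries under 1/3 of the median total, applied to 0 libraries.

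Over the 2145 pairs of libraries the lowest chi-square was 2.72 per degree of freedom over genes, so no pair agreed within sampling noise and all 66 were counted apart. The fits were tested on simulated counts of 10916 genes with the real means and depths, and with dispersions estimated per gene and capped. Genes were drawn independently, so variation shared between genes, such as the leading axis, was absent. The recoveries and false calls below hold for that setting only. In the real libraries with shuffled hours, the time effect test called a median of 35 genes and at most 916. With 50 genes changed by each fold, the linear trend test recovered 22% at 1.5-fold and 62% at 2-fold, with 3 false calls. The time effect test recovered 2% and 24% of the same trends, also with 3 false calls. The test of pools against individuals recovered 70% and 84%, with 4 false calls. A simulated dispersion ratio of 0.5 was estimated as 0.507, and a ratio of 1 as 0.981.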

Results

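Gene expression was measured in whole adults of the starlet sea anemone Nematostella vectensis that had been placed in a tidally restricted marsh pool and sampled every hour through one day. The 10 time points ran from 8 h to 17 h on the clock, which the labels give as ZT3 to ZT12. Of the 66 libraries, 37 came from single animals and 29 from pools of 2 animals. Most hours held 4 individual and 3 pooled libraries. ZT4 held 1 individual and 3 pooled libraries, and ZT6 held 4 individual and 2 pooled libraries. Library totals ran from 251647 counts in the ZT4 individual library C to 909746 counts in a ZT9 individual library, with a median of 640195. Individual libraries held 646134 ± 127400 counts (SD, n = 37) and pooled libraries 656333 ± 99780 counts (SD, n = 29). Mean totals were highest at ZT7, ZT8 and ZT9, at 725300, 753700 and 742300 counts. A total of 10916 of 24265 gene models had enough counts to be tested. The files give gene model identifiers and do not pair them with gene names, so genes appear here by identifier and no function is given.

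The first comparison asked which transcripts changed over the sampled day. In all, 2387 gene models (21.9% of those tested) differed between hours at an adjusted p below 0.05 in edgeR's quasi-likelihood test, with sample type in the model. NVE3844 rose and fell more than once in the day. It stood at 84.6 ± 39.3 CPM at ZT3 (SD, n = 7), 33.5 ± 9.9 at ZT4 (n = 4), 120 ± 31.8 at ZT6 (n = 6), 35.3 ± 8.39 at ZT9 (n = 7) and 97.7 ± 27 at ZT12 (n = 7), with an edgeR adjusted p of 1.51e-07. NVE12135 stayed near 19.3 ± 5.76 CPM at ZT3 (SD, n = 7) and 18.4 ± 6.1 at ZT6 (n = 6), then reached 45.4 ± 4.94 at ZT9 (n = 7). It stood lower at ZT10, at 30.4 ± 14.4, and at 53 ± 7.03 at ZT12 (n = 7 each), with an edgeR adjusted p of 1.55e-07. Between its highest and lowest hour, the median changed gene differed 2.34-fold, with quartiles of 1.89-fold and 3.23-fold. These folds are likely too large, since noise widens the gap between the extremes of 10 fitted hours and the genes were picked by the same test. The folds of genes that did not pass are not given here. Of the changed genes, 698 (29.2%) were lowest at ZT9, against 11.4% of the genes that did not pass. The reverse held for the peak, since 13.9% of the changed genes were highest at ZT9, against 20.6% of the genes that did not pass.

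**Figure D1:**
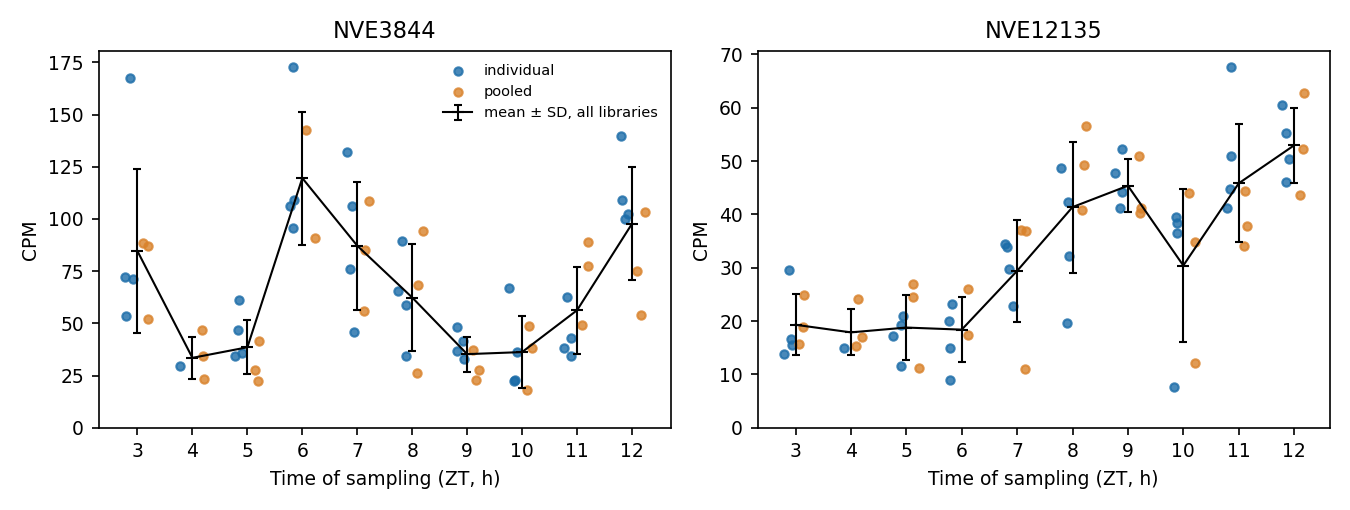
Normalised counts (CPM, vertical axis) of NVE3844 and NVE12135 against the hour of sampling (ZT, horizontal axis). Each point is a library, blue for single animals and orange for pools of 2, and the black line joins the means of all libraries at an hour with bars of 1 SD. NVE3844 was highest at ZT6, at a mean of 120 CPM. NVE12135 went from 19.3 CPM at ZT3 to 53 CPM at ZT12, with a lower mean of 30.4 CPM at ZT10.

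The identifiers with the smallest p among the falling genes owed their signal to few libraries. NVE3853 and NVE25154 fell between ZT3 and ZT12, with log2 changes of -7.62 and -6.36 (SE 1.37 and 1.28, edgeR adjusted p = 0.000441 and 0.0013). Their counts came almost wholly from 4 libraries, which were ZT3 individual B, ZT4 individual C, ZT4 pooled E and ZT5 pooled E. NVE3853 reached at least 468 CPM in each of these 4 and at most 6.66 CPM in any of the other 62. Without these 4 libraries its time effect had an adjusted p of 0.669, and that of NVE25154 had 0.747, in the same edgeR test. Over all genes tested, edgeR then called 2248 changed genes without the 4 libraries, of which 2025 were among the 2387. With all 66 libraries, limma with quality weights gave NVE3853 and NVE25154 adjusted p of 0.819 and 0.333.

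The changed genes were sorted by shape into 4 profiles with k-means on their fitted hourly values. Profile 1, with 981 genes (41.1%), was high from ZT3 to ZT6, with a median of 0.43 log2 units above the gene's mean at ZT5. It then declined to -0.55 at ZT9, returned to 0.05 at ZT10 and stood at -0.35 at ZT12. Profile 2, with 681 genes (28.5%), ran from -0.4 at ZT4 to 0.41 at ZT9 and stayed at 0.22 at ZT12. Profile 3, with 389 genes (16.3%), was highest at ZT6 (0.41) and lowest at ZT9 and ZT10 (-0.36 at both). Profile 4, with 336 genes (14.1%), was highest at ZT4 (0.53), the hour with 4 libraries. The profiles held 47.9% of the variance of the standardised hourly values, and their number was chosen after the data were seen.

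**Figure D2:**
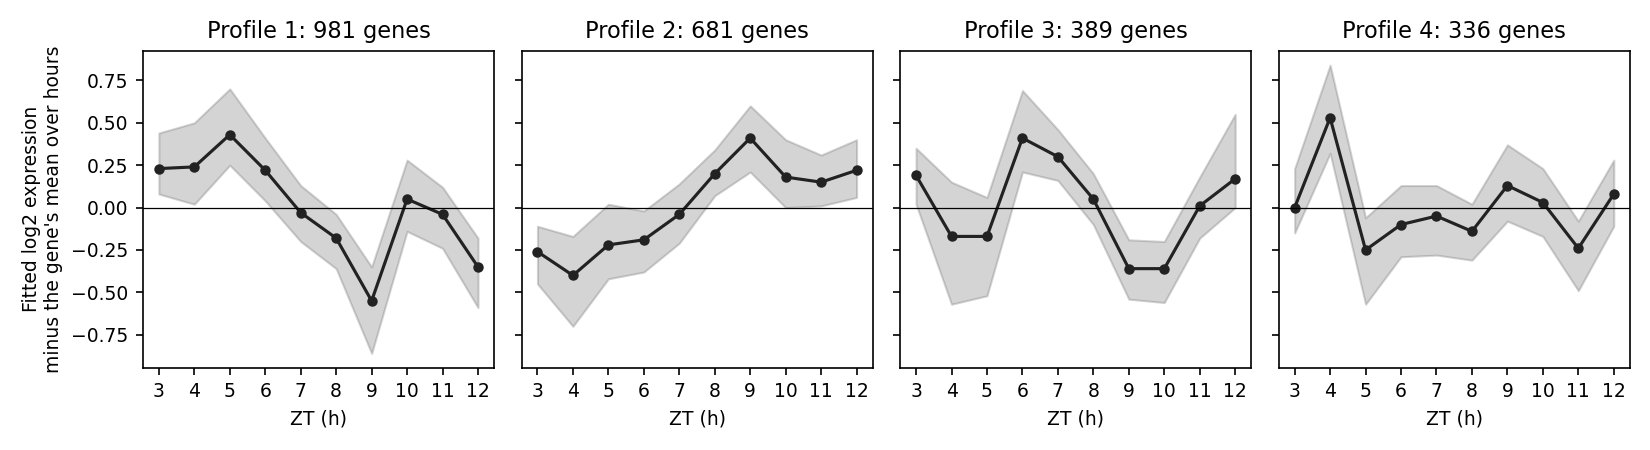
Fitted log2 expression minus the gene's own mean over hours (vertical axis) against the hour of sampling (ZT, horizontal axis), for the 4 profiles of the 2387 genes that differed between hours. Points are medians over the genes of a profile and the grey band spans the quartiles over genes. Profile 1 reached its lowest median, -0.55, at ZT9, where profile 2 was at its highest, 0.41.

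Consecutive hours were then compared to find when in the day transcript levels moved. The 9 steps together gave 765 calls. From ZT9 to ZT10, 303 genes rose and 25 fell, with a median absolute change of 1.11 log2 units among them. Without a filter on low counts this step held 164 rises and 12 falls. The step before it, from ZT8 to ZT9, held 5 rises and 55 falls. In the morning 18 genes rose and 0 fell from ZT3 to ZT4, 58 rose and 140 fell from ZT4 to ZT5, and 111 rose and 36 fell from ZT5 to ZT6. From ZT10 to ZT11, 8 genes rose and 6 fell. The smaller steps depended on the tool. From ZT3 to ZT4, where 608 genes had an unadjusted p below 0.05 and a lower level in edgeR, limma with quality weights called 77 rises and 26 falls and DESeq2 40 and 25. The 2 tools gave 188 rises and 320 falls, and 98 and 161, from ZT4 to ZT5, and 42 and 44 calls in all from ZT10 to ZT11. From ZT8 to ZT9 they gave 106 and 103 calls in all, and from ZT9 to ZT10 285 and 355. No gene passed edgeR's test from ZT6 to ZT7, ZT7 to ZT8 or ZT11 to ZT12, where 755, 887 and 1088 genes had an unadjusted p below 0.05. In these 3 steps limma with quality weights called 0, 0 and 54 genes and DESeq2 called 0, 4 and 35. The total of 765 rested partly on single libraries, since it was 498 without ZT10 pooled E and 1152 without ZT10 pooled F. Without the filter it was 427, and with limma and quality weights 1245.

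**Figure D3:**
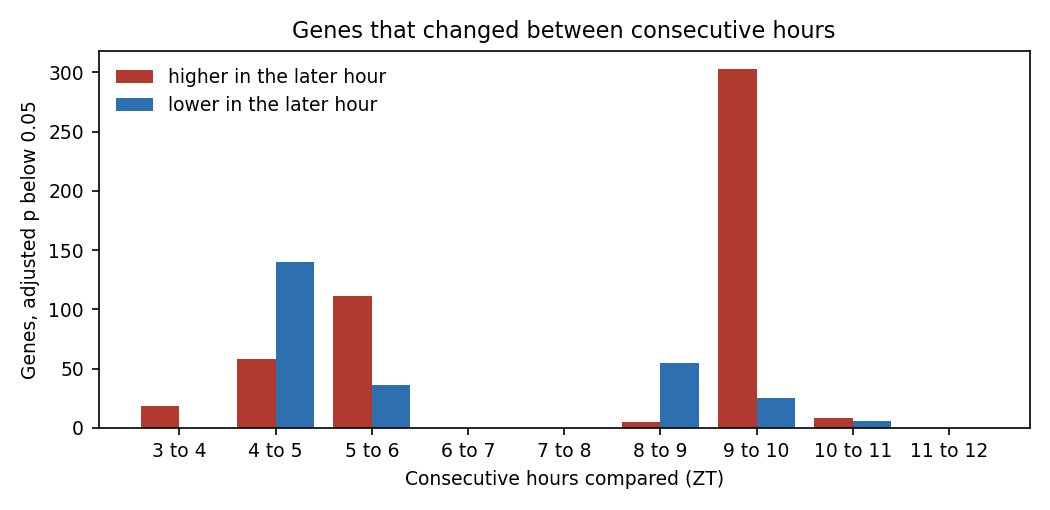
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test (vertical axis) for each pair of consecutive hours (ZT, horizontal axis). Red bars count genes higher in the later hour and blue bars genes lower in it. The step from ZT9 to ZT10 held 303 rises and 25 falls, and the steps from ZT6 to ZT8 held 0.

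Linear change over the sampled hours was tested with a linear term in ZT hour. In this test 716 genes rose and 903 fell, and 1110 of these 1619 genes also passed the time effect test. The test took libraries as replicates of the slope, with 62 residual degrees of freedom, although the slope rests on 10 hours. Shifts shared by the libraries of an hour, such as those of a pen, had no term in the fit. The p-values may therefore be too small, and a steady change was not told apart from a chance order of such shifts. The median rising gene gained 1.65-fold over the 9 h on the fitted line, with quartiles of 1.47-fold and 1.9-fold. The median falling gene ended at 0.591 times its starting level, with quartiles of 0.477 and 0.675. The steepest rises were those of NVE3803, at 0.342 log2 units per h (SE 0.115, edgeR adjusted p = 0.0346), and NVE6446, at 0.32 (SE 0.099, edgeR adjusted p = 0.0212). Both were patchy between libraries, and NVE3803 was 1 of 811 genes that shared the leading axis of variation between libraries. NVE3803 had no count in 37 of the 66 libraries and NVE6446 none in 24, and at ZT12 they stood at 35.2 ± 65.8 and 69.1 ± 66.1 CPM (SD, n = 7). The slope of NVE3803 no longer passed without ZT12 pooled G (0.204, edgeR adjusted p = 0.257) or in DESeq2 (adjusted p = 0.13), and that of NVE6446 did not pass in DESeq2 (adjusted p = 0.0668). Limma with quality weights gave slopes of 0.174 and 0.244 (adjusted p = 0.286 and 0.357), and without ZT4 the edgeR adjusted p were 0.0894 and 0.0714.

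The steepest falls were those of NVE5055, at -1.455 log2 units per h (SE 0.279, edgeR adjusted p = 0.000689), and NVE6036, at -1.191 (SE 0.131, edgeR adjusted p = 2.34e-10). Both belonged with NVE3853 in the same 4 libraries. NVE5055 had no count in 60 of the 66 libraries, and NVE6036 stayed at or below 9.95 CPM outside the 4 and reached 3110 CPM within them. Without the 4 libraries the slope of NVE5055 was -0.0139 (edgeR adjusted p = 0.946) and that of NVE6036 was 0.0276 (edgeR adjusted p = 0.844).

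A curved course with its turn near midday was tested with a quadratic term. It passed for 3 genes with a midday peak and 1 with a midday trough. At an unadjusted p below 0.05 there were 437 genes with a peak and 391 with a trough, where 546 in all would be expected by chance alone, and the power of this term was not simulated. NVE19553 went from 10.6 ± 4.65 CPM at ZT3 (SD, n = 7) to 48.4 ± 10 at ZT9 and 30.1 ± 7.85 at ZT12 (edgeR adjusted p = 0.0214). NVE7544 stood at 0.815 ± 1.53 CPM at ZT3, 25.2 ± 42.3 at ZT8 and 4.06 ± 6.63 at ZT12 (SD, n = 7, edgeR adjusted p = 0.0214), and it had no count in 29 libraries. NVE18680, the gene with a trough, went from 106 ± 48 CPM at ZT3 to 39.1 ± 7.16 at ZT7 and 59 ± 10.1 at ZT12 (SD, n = 7, edgeR adjusted p = 0.0214). Most of its fall came before ZT4, where it stood at 50.3 ± 3.37 CPM (SD, n = 4). Each of these calls was lost when single libraries were left out, for example ZT3 pooled F, without which the edgeR adjusted p was 0.0695 for NVE7544, 0.0659 for NVE19553 and 0.0872 for NVE18680. NVE7544 did not pass in DESeq2 (adjusted p = 0.0956) or in limma with quality weights (adjusted p = 0.659).

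Between the first and last hour, ZT3 and ZT12, 133 genes rose and 255 fell in the edgeR fit of the time effect. Without a filter on low counts 85 rose and 106 fell, and with counts thinned to a lower depth 82 and 161. NVE12135 rose by 1.44 log2 units (SE 0.24, edgeR adjusted p = 0.000441) and NVE19553 by 1.5 (SE 0.32, edgeR adjusted p = 0.00445). NVE18680 fell by 0.84 (SE 0.24, edgeR adjusted p = 0.0347). Leaving out single libraries of the end hours lowered the rises to 81 without ZT3 individual A, 72 without ZT3 individual C, 79 without ZT12 individual D and 88 without ZT12 pooled G. The falls went to 146 without ZT3 individual C, 169 without ZT12 individual A, 152 without ZT12 individual D and 155 without ZT12 pooled G.

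The series sampled single animals and pools side by side, so the level of each gene was compared between the 2 kinds of library with the hour in the model. No gene passed edgeR's quasi-likelihood test in either direction, and the smallest adjusted p was 0.464. At an unadjusted p below 0.05 there were 324 genes higher and 273 lower in pools, 597 in all, where 546 of 10916 would be expected by chance alone. DESeq2 and limma with quality weights also called 0 genes. The median absolute difference was 0.0947 log2 units, with a median SE of 0.141. Leaving out ZT9 pooled E gave 3 genes lower in pools. In simulated counts of independently drawn genes, with 50 changed by each fold, this test recovered 70% of the genes changed 1.5-fold and 84% of those changed 2-fold.

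The time course differed between pools and single animals for 16 genes in the interaction test. NVE3853 and NVE25154 were among them, with edgeR adjusted p of 0.00125 and 0.00259, as was NVE6036 with 0.00167. These 3 are high in the same 4 libraries, as are 12 of the 16 genes. NVE7544, which is not, had an adjusted p of 0.0429. Without those libraries the interaction test gave 0 genes. The count also went to 0 without ZT5 pooled E, to 6 without ZT5 individual D, to 7 without ZT3 pooled F and to 8 without ZT3 pooled G. It rose to 30, 32 and 34 without ZT3 individual A, C and D, to 26 without ZT4 pooled E, and to 30 and 31 without ZT5 pooled F and G. Limma with quality weights called 4 genes.

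The time effect was also tested in each kind of library alone. Single animals gave 933 genes over 37 libraries and pools gave 69 over 29 libraries, with 45 genes in both lists, where independent lists would share 5.9. The 4 libraries above include single animals and pools, so genes high in them can enter both lists. How many of the 45 are such genes was not counted, so this overlap alone does not show a shared effect of the hour. Of the 933 genes, 382 (40.9%) had an unadjusted p below 0.05 in the edgeR test of pools. The same share over all tested genes was not counted, so how far 40.9% exceeds the background is not known. With replicates A, B and C alone, which bring single animals to 3 libraries at most hours, 354 genes passed. The 69 genes of the pools fell to 1 without ZT4 pooled E and ZT5 pooled E, the pools among the 4 libraries above, while DESeq2 called 385. The count also depended on single pools, and was 107 without ZT4 pooled D, 40 without ZT4 pooled E, 33 without ZT4 pooled F, 126 without ZT7 pooled E, 44 without ZT8 pooled G and 133 without ZT10 pooled E. Whether the 2 kinds of library differed in their time course was tested gene by gene by the interaction above.

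Spread between libraries of one hour was compared between the 2 kinds of sample. The biological coefficient of variation, the square root of edgeR's common dispersion, was 38% between single animals and 42.8% between pools. The dispersion was 0.144 for single animals and 0.183 for pools, a ratio of 1.27. A 2 SE interval from leaving out each library in turn ran from 0.766 to 2.11. The median over genes of the ratio of residual variances was 1.16, and a two-sided permutation test of sample type within the hour gave p = 0.184 over 10000 draws. Without the 4 libraries named above, a setting chosen after the data were seen, the dispersion ratio was 1.41. The permutation test of residual variances gave p = 0.036 in that setting, over 1000 draws.

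Single animals taken at the same hour differed widely in some transcripts. The residual SD of log2 CPM around the hour mean had a median of 0.483 over genes, and 676 genes (6.19%) exceeded 1. This count depended on the prior count of 2 added before taking logs, and was 1320 with a prior count of 0.5. The 2 genes with the largest SD were NVE20622 and NVE9958, at 3.65 and 3.5 log2 units over 37 libraries. NVE20622 had at most 10 counts in 23 individual libraries and at least 100 in 13, with a highest count of 2973. NVE9958 had at most 10 counts in 24 and at least 100 in 12, with a highest count of 1643. Of the 676 genes, 396 had more than 49% of their residual variance on one axis of variation between libraries and ran in its positive direction. This overlap is partly built in, since genes with a large residual SD weigh most in that axis.

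**Figure D4:**
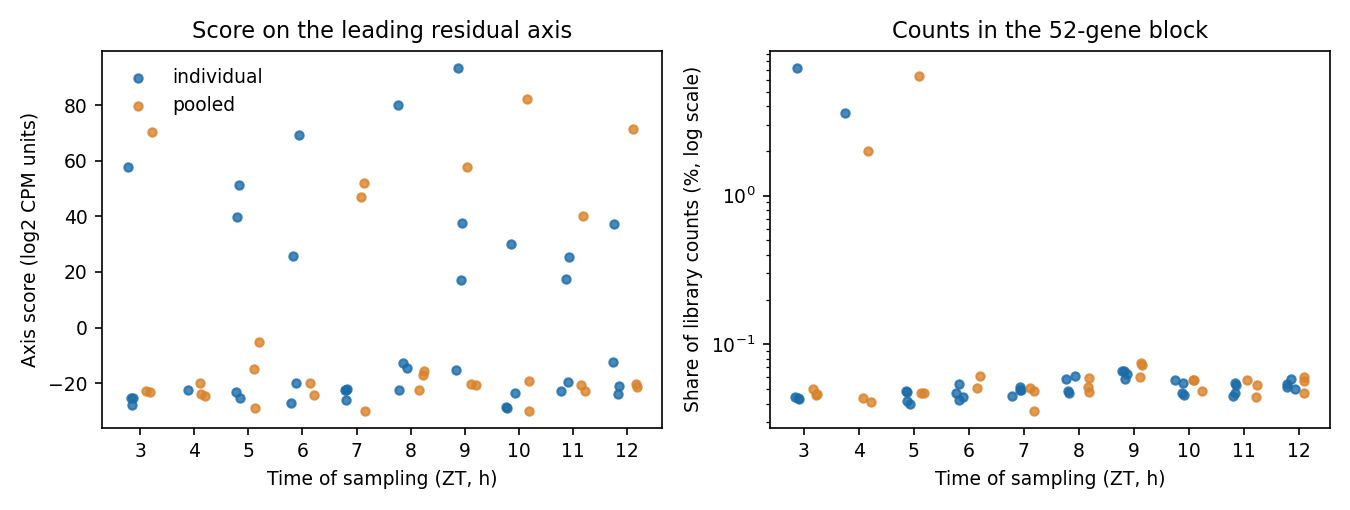
Left, score of each library on the leading axis of residual variation in log2 CPM (vertical axis) against the hour of sampling (ZT, horizontal axis). Right, share of each library's counts in the 52 genes that were higher in 4 early libraries than in any other (percent, log scale). Points are libraries, blue for single animals and orange for pools of 2. Scores lay either at or below -5.16 or at or above 17.2, and the block held 2.01% to 7.23% of counts in 4 libraries and at most 0.0744% in the others.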

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

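The tests in this part, the splits included, were written down after the results they bear on had been seen. Library totals, gene models detected, axis scores, block shares and CPM of the named genes were compared within each group of 4 single animals. A library was picked out when its gap to the nearest other exceeded the 95% limit of Dixon's test. Of 135 group and measure pairs 32 were picked out. Chance picks out about 1 in 20 groups of continuous, independent values, but that share does not hold here. A few counts always stand apart from 3 libraries at 0, and the genes are related and partly patchy.

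ZT3 individual B stood apart in several measures. It had 17934 gene models with a count against 16721 to 16829 in the other 3, an axis score of 57.84 against -27.84 to -25.29, and 7.229% of its counts in a block of 52 genes against 0.04295% to 0.0445%. Its CPM was 2237 for NVE3853, 668.9 for NVE25154, 311.6 for NVE5055, 2687 for NVE6036 and 21.83 for NVE3803, where the other 3 reached at most 8.672. On the axis, ZT8 individual D scored 80.01, ZT10 individual B 30.25 and ZT7 individual A -25.92, the first 2 above and the last below the other 3 of its hour.

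The other gene values that stood apart were mostly high values in one animal, some of them a few counts against 0. NVE3803 stood at 26.32 CPM in ZT5 individual B, 73.65 in ZT8 individual D, 61.89 in ZT10 individual B, 17.64 in ZT11 individual A and 61.89 in ZT12 individual C. NVE6446 stood at 24.56 CPM in ZT5 individual B, 4.567 in ZT7 individual A and 172.9 in ZT11 individual D, and was low in ZT6 individual B, at 3.638 against 13.65 to 15.59 in the other 3. NVE7544 stood at 1.368 CPM in ZT8 individual A, 1.53 in ZT11 individual C and 16.79 in ZT12 individual A. NVE25154 stood at 7.666 CPM in ZT5 individual C, 2.424 in ZT9 individual A and 1.317 in ZT12 individual C. NVE3853 stood at 1.491 CPM in ZT11 individual D and NVE6036 at 6.841 CPM in ZT10 individual C. Among the more abundant genes, NVE3844 stood at 167.7 CPM in ZT3 individual D, NVE12135 was low at 7.662 CPM in ZT10 individual A against 36.49 to 39.61 in the other 3, and NVE18680 stood at 98.23 CPM in ZT6 individual B and 60.39 CPM in ZT8 individual C.

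The time course differed between pools and single animals for 16 genes. Shuffling sample type within the hour gave as many in 26 of 100 splits, with a highest other count of 357, so chance could not be excluded.

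A block of 52 genes was high in 4 early libraries. These genes had a higher CPM in each of ZT3 individual B, ZT4 individual C, ZT4 pooled E and ZT5 pooled E than in any of the other 62 libraries, and 13 of the 20 smallest p of the time effect belonged to them. The hour of sampling alone was argued against, since 14 of the 18 libraries taken from ZT3 to ZT5 lacked the block. RNA of ZT3 individual B carried into the others was also argued against, since their block shares would then bring the genes of the leading axis to 68.5% (ZT4 individual C), 54.7% (ZT4 pooled E) and 92.7% (ZT5 pooled E) of its level, where 31.7%, 40.5% and 37.9% were found and libraries low on the axis held 30.9% to 43%. Carry-over from a library other than ZT3 individual B, material from another source and a state of particular animals stay open, and no biological explanation was tested because the identifiers are not paired with names.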

How the results depend on the processing

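A total of 121 summary values under another setting were compared with their main value, single left-out libraries aside. Of these, 99 stayed within 1.5 times the main count or on the same side of the threshold. The 99 include the counts of genes differing between pools and individuals, which stayed at 0. A count that stayed can also hold other genes. Without a filter on low counts, 1849 of the 2387 time effect genes and 1166 of the 1619 genes with a linear trend were called again. The cause of the exceptions was not tested unless stated. For the named genes 84 of 107 such comparisons kept the call, 22 lost it with the same sign and 1 turned its sign. Without a filter on low counts there were 5 midday peaks, 0 midday troughs, 85 rises and 106 falls from ZT3 to ZT12 and 427 hour-to-hour calls. Limma with quality weights gave 3 midday troughs, 1245 hour-to-hour calls and 4 interaction genes. DESeq2 gave 2 midday troughs and 385 time effect genes in pools. Replicates A, B and C alone gave 354 time effect genes in individuals, with fewer samples. Of the settings chosen after seeing the data, leaving out the 4 libraries with the early gene block gave 7 midday peaks, 4 midday troughs, 0 interaction genes and 1 time effect gene in pools. It also gave a spread ratio of 1.414 (p = 0.036 in the permutation test of residual variances) and a slope of 0.0276 for NVE6036, the one sign that turned. The axis score as covariate gave 3 midday troughs and 137 time effect genes in pools. Thinning to a lower depth gave 2 midday troughs, 82 rises and 161 falls from ZT3 to ZT12, with fewer counts.

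With the replicate letter as a block in place of sample type there was 1 midday peak. The other counts run with this block, which are those of hour effects in all libraries or in one sample type, moved by at most 1.5 times, with 2333 time effect genes, 684 linear rises and 856 linear falls. The midday calls of NVE7544 and NVE19553 passed no longer (edgeR adjusted p = 0.0684 for both), with coefficients of -10.8 against -11.38 and -3.159 against -3.237. The letters showed no pairing of the libraries. Between libraries of different hours, residuals had a mean correlation of 0.005 for the same letter and 0.0023 for different letters. Of 279 same-letter pairs 105 had residuals correlated above 0.1, a share not counted for different letters. In all, 11 of 66 libraries were closest to their own letter.

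Leaving out each library in turn gave 2173 to 2737 time effect genes, 608 to 772 linear rises, 794 to 1014 linear falls, 1 to 6 midday peaks, 0 to 11 midday troughs, 72 to 145 rises and 146 to 296 falls from ZT3 to ZT12, and 498 to 1152 hour-to-hour calls. It gave 0 genes above and 0 to 3 below individuals in pools, 0 to 34 interaction genes, 729 to 1035 time effect genes in individuals, 33 to 133 in pools, and a spread ratio of 1.15 to 1.414. Midday troughs were 0 without ZT3 individual A, ZT3 pooled F or ZT12 individual A, and 11 without ZT5 pooled E. Gene list tests and the setting without libraries under 1/3 of the median total were not run, the former for lack of gene names and the latter because no library met it. In simulated counts of independently drawn genes at the depth and sample number of these data, 1.5-fold trends were recovered at 22%. Which of depth, spread and sample number limits this was not simulated. Thinning the real counts to at most 424453 per library, the second lowest total, gave 1875 time effect genes.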

Other observations

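The tests in this part, the splits included, were written down after the results they bear on had been seen. The leading axis of variation between libraries was computed with hour and sample type removed, and it carried 29.5% of the residual variance, against 5.59% for the next. Scores fell into separate ranges, with 46 libraries from -29.9 to -5.16 and 20 libraries from 17.2 to 93.4. The upper range held 13 of 37 single animals and 7 of 29 pools. A total of 811 genes ran up the axis with more than 49% of their residual variance on it, and 6 ran down it. NVE20622 and NVE9958, the most variable genes between single animals, were among the 811, which is partly built in because such genes weigh most in the axis. At ZT9, 4 of 7 libraries were in the upper range, against 2 of 7 at ZT10. Sex and reproductive state of the animals are not given in the labels used here, so what the axis stands for was not tested.

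Other groupings of the libraries were drawn to see how often chance gave as many genes, with 100 splits for each result. Shuffling the hours within sample type gave as many genes as the real hours in 1 of 100 splits, the real one, for the time effect (2387, highest other 916), for linear rises (716, highest other 470), for linear falls (903, highest other 192) and for falls from ZT3 to ZT12 (255, highest other 26). The rises from ZT3 to ZT12 were matched in 2 of 100 (133, highest other 207) and the hour-to-hour calls in 4 of 100 (765, highest other 1564). The time effect in single animals was matched in 1 of 100 (933, highest other 784). All of these lay under a limit of 5 in 100, set after the results were seen, for 13 results and without correction for their number. Where only the real split gave as many genes, the lowest share that 100 splits can show, this argues against libraries falling into hours by chance. The splits moved libraries one by one, so shifts shared by the libraries of an hour, such as those of a pen, could also exceed them. Whole hours were not shuffled, so for the linear rises and falls a chance order of such shifts was not excluded. For the rises from ZT3 to ZT12 and the hour-to-hour calls chance was not excluded, since some splits gave more genes than the real hours. Nor was it excluded for the midday peak, matched in 12 of 100 splits (3, highest other 104). The same held for the midday trough, in 23 of 100 (1, highest other 99), and the time effect in pools, in 15 of 100 (69, highest other 441). Genes higher or lower in pools numbered 0, so 100 of 100 splits gave as many, with highest other counts of 553 and 27. Splits with several times the real count point to a structure among the libraries. Whether it is the leading axis or the hour effect that shuffling leaves in the data was not tested.

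The dispersion of pools of 2 animals was 1.27 times that of single animals. Leaving out the 4 libraries with the early gene block did not lower the ratio (1.414), nor did thinning all libraries to one depth (1.281). Both values lie inside the 2 SE interval of 0.766 to 2.11. The permutation test of residual variances did not tell pools from single animals (p = 0.184). Neither cause can therefore be judged from these shifts. Equal mixing of 2 animals allows a ratio from 0.5, if all spread lies between animals, to 1, if it arises in library preparation. Unequal mixing also keeps the ratio between 0.5 and 1, so the spread cannot tell the 2 kinds of mixing apart. The lower 2 SE bound of 0.766 lies inside that range, so neither is argued against. In the upper range of the axis were 7 of 29 pools and 13 of 37 single animals (Fisher's exact p = 0.422, two-sided). If a pool scored high whenever either of 2 randomly drawn animals did, with a share of 22% fitted to both kinds of library, a gap this large came in 0.7% of 10000 simulated draws, but whether a mixed pool scores high and whether pooled animals were drawn at random was not tested.

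The rise of 303 genes from ZT9 to ZT10 coincided with more libraries high on the axis and deeper libraries at ZT9. TMM factors also differed, from 1.041 to 1.158 at ZT9 and from 0.908 to 1.061 at ZT10. Whether this difference in library composition bears on the step was not tested. With the axis score in the model 178 of the 328 calls of this step remained, and the median absolute change of the 150 lost went from 0.999 (quartiles 0.736 and 1.44) to 0.873 log2 units (0.658 and 1.24), at a median SE of 0.276 and 0.275. With deeper libraries thinned to 424453 counts, and ZT4 individual C left at its 251647, 205 remained, and the median absolute change of the 123 lost went from 0.977 (quartiles 0.73 and 1.29) to 0.931 (0.698 and 1.19), while the median SE went from 0.275 to 0.305. All lost genes kept their sign in both fits. Most of the change remained with the axis score in the model, so the score as a linear term is not the whole cause of the step. Thinning finished counts leaves the expected CPM as it was. It shows how depth affects the calls but cannot test a bias that went with depth at ZT9. A bias tied to depth, a difference between pens or handling at ZT9, and a change with the hour or the tide stay open and untested.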
